A study of Mus musculus with 8 samples.

How the data were processed

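Per the labels, leukocytes of the liver and the bone marrow of C57Bl6/J mice on a normal diet (ND) or a Western diet (WD, rich in fat, sugar and cholesterol) were isolated by collagenase digestion. They were sorted as CD45+ cells without Ly6G, CD3, CD4, CD19 or NK1.1, 50000 cells per sample, and made into 10x single-cell libraries. The 8 samples fall into 4 groups of 2, ND and WD in each of 2 tissues. The labels give the diet as 24 weeks from 8 weeks of age in one place, and as 16 weeks at an age of 24 weeks in another.

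The deposited values are raw UMI counts per gene and cell, in 1 table per tissue that joins its 4 samples. They are whole numbers, and every gene listed was seen in at least 3 cells. Per the submitters' processing notes, Cell Ranger, Seurat 2.3.0 and the mouse build mm10 were used; the notes do not give the role of each. For part of the cells the deposited annotation names a cell type, and how the types were assigned is not stated. The types MoMF, KC, BMM, CMoP and preDC are not spelled out in the labels and are described here by their genes. The type "CDC2 III" is written cDC2 III.

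In each tissue the cell barcodes end in 1 of 4 numbers, called barcode sets 1 to 4 here. No label ties a barcode set to a sample, a diet or a replicate, and none was guessed from the values. The comparisons of WD with ND planned before the data were examined could therefore not be run. These were the edgeR tests per type and over all cells, the tissue by diet interaction, the tests of cell shares by diet, and camera and fry on the gene lists. What remained were comparisons between annotated types within a tissue and between like types of the tissues. They were chosen after a first look at the type profiles.

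UMIs were summed per gene, type and barcode set over the annotated cells and divided by their total, to give CPM (UMIs per 1000000 UMIs). For 2 types A and B of a tissue, the fold was log2((CPM of A + 10)/(CPM of B + 10)) within each barcode set. It is given as the median over the 4 sets with the lowest and highest set. Between tissues, it is the median over the 16 pairs of a liver with a bone marrow set, over the 14491 genes of both tables. Barcode sets are not known to be replicates of a group, so no p-value, standard error or count of changed genes over all genes is given. A gene lies the same way in all 4 sets by chance with a probability of 12.5%. This assumes that either direction is as probable in each set and that the sets are independent. In simulated data with a common shift of the unchanged genes the share was higher. Complete separation of 4 from 4 sets has a chance of 2.86%. Types were summed into classes where they share a name, as for MoMF I, II and III. Class values weight types by their UMIs, so each class comparison was repeated with each type of the class in its place, which was chosen after seeing the data.

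The 22 gene lists were fixed before the data were examined, 6 of them with markers of other cell types, most of which the gate should remove. A list member was counted as measured at 10 CPM or more in either type, and as higher or lower at a median fold of 2 or more with the same direction in all 4 sets or 16 pairs. The median fold of a list was ranked among those of 10000 random lists of genes with like mean level (seed 7), for lists with at least 5 measured members, and its rank is given as a percentile. Genes in a list are not independent. The genes named are the 10 with the largest fold each way among those with at least 50 CPM in the higher type, the same direction throughout and more than 3 counts in the lower type. To these come up to 4 per list, and in each comparison S100a8, S100a9, Trem2, Gpnmb, Clec4f, Timd4, Il1b, Tnf, Ccl2, Cd36, Apoe, Hmgcr and Ldlr were computed. Members named beside a count of 5 or fewer can lie outside this rule and were chosen after their values were seen. The rule replaced one that rested on the diet tests, and was set after a first look at the type profiles. S100a8 and S100a9 are known to have been picked by the study from these libraries, so the calprotectin list is not independent evidence of its direction.

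Shares of cells have 95% Clopper-Pearson intervals, which cover counting error only. The cells without a deposited type were clustered per tissue over 2000 variable genes, 30 principal components, 20 neighbours and the Leiden method at resolution 1.0. A cluster was named after a marker class only where at least 3 of its markers stood at 50 CPM or more and 4-fold above the other cells of the tissue, at least 2 of them lay among the 10 genes with the largest fold, and no other class had 2 there. No program for doublets was run. Gene positions are those of GENCODE for GRCm38, which is mm10.

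The calls were tested on simulated data in 3 comparisons, with counts drawn from Poisson distributions, so with counting error only. In each, 100 genes were changed 4-fold, 100 were changed 2-fold and the others were left unchanged. All levels were then rescaled to a common total. Of the genes with a 4-fold difference, 99% to 100% were called at 2-fold. Of those with a 2-fold difference 16% to 27% were, since the pseudocount pulls folds toward 0. No unchanged gene was called, but 19.9% to 70.3% of these lay the same way in all sets. The rescaling gave the unchanged genes a small common shift, so this share is not a chance rate. A common direction alone was not read as a difference.

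The alternatives tried were median-of-ratios scaling, no filter on low levels, each cell thinned to 1500 UMIs, and for bone marrow shares a denominator without HSC. Chosen after seeing the data were pseudocounts of 1 and 100 CPM, cells of all barcode sets summed, the median of the 4 sets for shares, and leaving out each barcode set in turn. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.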

Results

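Single cells were profiled from 8 samples of sorted liver and bone marrow leukocytes in 4 groups of 2, mice on a normal diet (ND) and on a Western diet (WD) in each tissue. The liver table held 13543 cells and 15366 genes, and that of bone marrow 13927 cells and 15462 genes. A type was given for 10356 liver cells (76.5%) in 10 types and for 10276 bone marrow cells (73.8%) in 9 types. Each tissue's cells fell into 4 barcode sets. Annotated liver cells numbered 2657, 1155, 3577 and 2967 in sets 1 to 4, with 13111032, 6931320, 21018699 and 17492897 UMIs. Annotated bone marrow cells numbered 2592, 2297, 2644 and 2743, with 23262704, 20174784, 22775207 and 23120813 UMIs. A median annotated cell held 5216 UMIs in liver and 6958 in bone marrow.

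The labels state the study's subject as the phenotype of liver and bone marrow myeloid cells in obesity-related steatohepatitis, with WD against ND as the contrast. That contrast could not be computed, because nothing in the labels ties a barcode set to a sample or diet. The comparisons made ask instead how the annotated myeloid types differ in each tissue and between tissues. Values are medians over the 4 barcode sets with the lowest and highest set in brackets. There are no known replicates of a group, and intervals cover counting error only. The types were defined by the authors, so genes that separate them are a description of the types and not independent evidence.

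MoMF, cells rich in monocyte genes such as Ly6c2 and F13a1, were the largest liver class with 4910 cells, 47.4% of those annotated (95% Clopper-Pearson interval 46.4% to 48.4%), and between 33.9% and 54.7% in single barcode sets. The dendritic cell classes followed, with cDC2 at 25.8% (22.8% to 27.4% over sets), cDC1 at 16.1% (9.34% to 27.1%) and pDC at 8.10% (6.68% to 9.63%). The order is that of pooled cells, and cDC1 exceeded cDC2 in set 1 (27.1% against 22.8%) and in set 2 (26.7% against 26.3%). KC, cells with Kupffer cell genes, were 2.56% (1.48% to 4.42%). In bone marrow, BMM made up 51.4% (47.8% to 55.6%), CMoP 26.9% (23.0% to 29.9%), preDC 15.2% (13.1% to 16.6%) and HSC 6.50% (4.96% to 7.75%). The liver cDC1 intervals of single sets did not all overlap, at 25.4% to 28.8% in set 1 and 8.31% to 10.4% in set 4. Shares refer to sorted cells with an annotated type, so the gate and the annotation set their denominator. Liver cells without a type, which are left out, numbered 1451, 751, 546 and 439 in sets 1 to 4. Liver shares by set therefore rest on unlike parts of the cells.

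**Figure D1:**
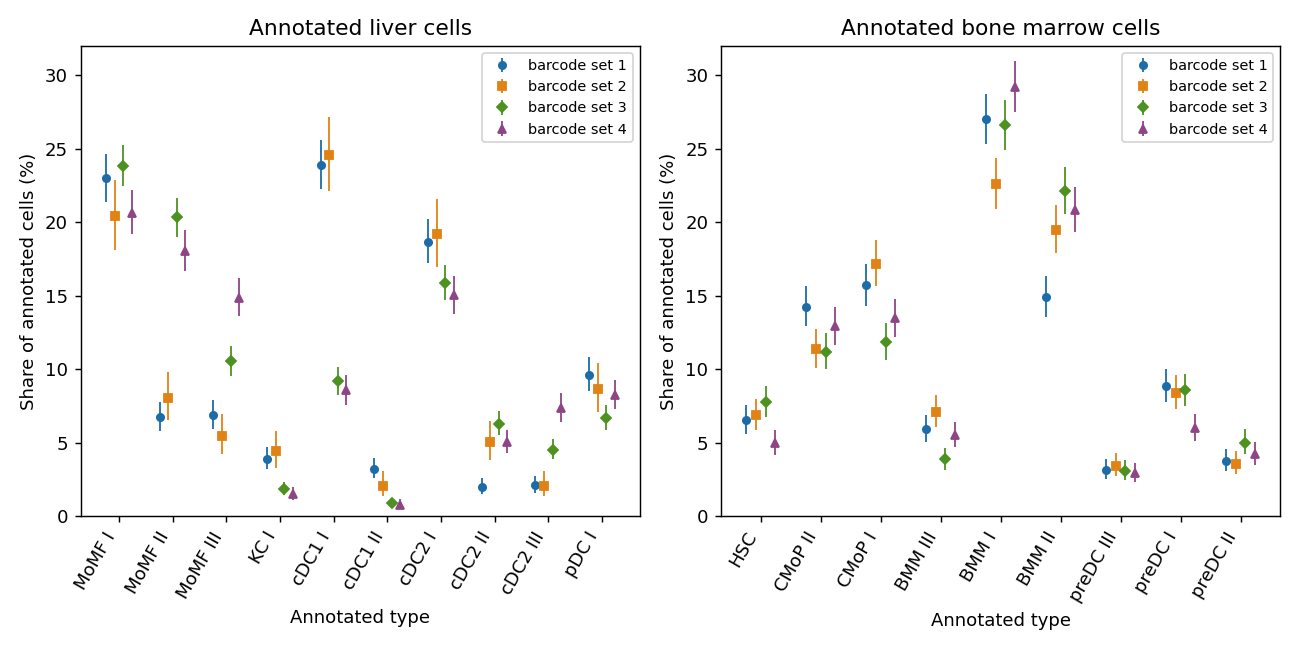
Share of each annotated type among annotated cells (%, vertical axis) by type (horizontal axis) in liver and bone marrow; each point is 1 of 4 barcode sets and bars are 95% Clopper-Pearson intervals. MoMF II spanned 6.74% to 20.3% of annotated liver cells and cDC1 I 8.56% to 24.6%, while BMM I spanned 22.6% to 29.2% of annotated bone marrow cells.

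KC carried more transcripts of most Kupffer cell identity genes, and of part of the complement and LXR target genes, than MoMF. Clec4f, a lectin receptor specific to Kupffer cells (chromosome 6, 83644542 to 83656187), stood at 582 CPM in KC and 7.39 CPM in MoMF, a log2 fold of 4.76 (3.38 to 5.84). The complement receptor Vsig4 (4.66, 2.36 to 5.59), the lectin Cd207 (4.63), the iron exporter Slc40a1 (4.44) and the phagocytic receptor Timd4 (1.99, 0.29 to 3.15) were higher as well. MoMF in turn had more of the monocyte genes Chil3 (-5.00, -5.55 to -3.98), F13a1 (-4.54), S100a4 (-4.53), Ly6c2 (-4.14) and Fn1 (-4.13). Of 20 measured Kupffer cell identity genes, 16 were higher in KC and 0 lower, with a list median of 2.28 (0.90 to 3.14). Of 15 complement and efferocytosis genes 9 were higher, led by the C1q chains C1qa (4.20) and C1qc (4.20), and 1, C3, was lower. C1qa was itself higher in MoMF II than in MoMF I, so its fold against the class mixes unlike types. Among 13 LXR targets 7 were higher, including the lipoprotein genes Apoe (2.94, 2.69 to 3.16), Apoc1 (3.38) and Pltp (2.37), and 0 lower. Granule genes were lower in 8 of 14 and inflammatory genes in 7 of 22, with Cxcl16 the 1 inflammatory gene higher (1.71). The inflammatory difference was largest against MoMF III, with 12 of 23 lower in KC, while 5 of 21 were lower against MoMF II and 0 of 21 lower and 3 higher against MoMF I, and Cxcl16 stood at 0.53 against MoMF II. The percentile among random lists was 100 for the lists that were higher and 0.00 for the granule and inflammatory lists. S100a8 did not separate the classes (-0.30, -1.06 to 0.02, and 0.54 with the cells of all sets summed). KC were few, with 44 to 104 cells per set, and the Timd4 fold rested on a level of 46.1 CPM. Without set 1 or without set 2 the fold was 5.49 for Clec4f, -3.94 for F13a1, 4.41 for Apoc1, 3.31 for Pltp and 2.91 for Timd4, and without set 3 or without set 4 it was 4.03 for Clec4f, -5.14 for F13a1, 2.36 for Apoc1, 1.43 for Pltp and 1.07 for Timd4. Hepatocyte transcripts differed too, with Alb, Apoa2 and Fabp1 higher and Hp lower among 9 measured. Without set 1, 6 were higher, and without set 2, 5 were. Hp also stood at 1245 CPM in BMM I of bone marrow, so its difference cannot be read as hepatocyte RNA alone. Of 4 measured endothelial and stellate genes, Fcgr2b was lower and the other 3 did not reach 2-fold. Of the neutrophil transcripts 3 of 11 were lower, but the median of this list changed sign with the cells of all sets summed. Of the dissociation and immediate early genes 4 of 22 were lower, or 17 of 22 against MoMF III, with 0 higher.

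Within MoMF, MoMF II differed from MoMF I by antigen presentation, complement and lipid-handling genes. MHC class II genes were higher in 10 of 13 and lower in 0, with a list median of 1.37 (1.16 to 1.56), H2-Eb1 at 3.22 (2.90 to 3.64) and the invariant chain Cd74 at 2.53. The lipid-associated macrophage list had 11 of 20 higher and 0 lower, with a median of 1.13 (1.06 to 1.21). Its members included the matrix protein Spp1 (3.61, 3.02 to 4.14), the tetraspanins Cd63 (2.75) and Cd9 (2.31), the glycoprotein Gpnmb (2.28, 1.91 to 2.79) and the fatty acid receptor Cd36 (1.57). Trem2, a lipid receptor of such macrophages, had no common direction over sets (-0.04, -0.27 to 0.73), at 111 CPM in MoMF II and 88.9 CPM in MoMF I. The chemokine Cxcl9 (4.60, 2.69 to 6.33), the interleukin 1 antagonist Il1rn (3.42) and C1qa (4.17) were higher, and 8 of 19 inflammatory genes were higher, or 5 without set 2. Without set 1 or set 2 the Cxcl9 fold was 3.24, and without set 3 or set 4 it was 5.96. Complement and efferocytosis genes were higher in 6 of 12 and lower in 0, with a median of 1.05 (0.84 to 1.26). Bcl2a1b also stood at 4.65, but the Bcl2a1 genes are near-identical copies whose reads cannot be assigned with certainty. MoMF I had more F13a1 (-1.63), Mgst1 (-1.69) and Chil3 (-1.29). The 4 lists counted here lay at percentile 100.

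MoMF III stood out by immediate early and inflammatory genes. Against MoMF I and II together, 19 of 22 dissociation and immediate early genes were higher and 0 lower, with a median of 2.09 (1.74 to 2.63). The phosphatase Dusp1 (3.34, 3.03 to 3.67) and the transcription factors Fos (2.83) and Nr4a1 (2.52) were among them. Inflammatory genes were higher in 16 of 22, with a median of 1.44 (1.43 to 1.67), led by the neutrophil chemokine Cxcl2 (4.24, 2.90 to 5.81) and the cytokines Il1b (3.54, 2.98 to 3.94) and Osm (3.06). Il1b (chromosome 2, 129364570 to 129371139) reached 3415 CPM against 300.1 CPM. Cxcl9 was lower, at -3.08 (-5.15 to -1.25; -1.55 without set 1 or set 2, -4.60 without set 3 or set 4), which came from MoMF II (-4.48) and not from MoMF I (-0.09). Both leading lists lay at percentile 100. The dissociation list holds genes that tissue digestion is known to induce, and no undigested liver cells were profiled.

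The 2 conventional dendritic cell classes of liver separated by their known receptors. The chemokine receptor Xcr1 (4.41, 4.37 to 4.96), the transcription factor Irf8 (3.34), the nucleic acid sensor Tlr3 (3.07) and the fatty acid receptor Cd36 (2.95) were higher in cDC1. The lectins Cd209a (-4.35, -4.61 to -4.25) and Clec10a (-3.72) and the chemokine Ccl5 (-4.92) were higher in cDC2, with Clec10a lowest in cDC2 II (-0.66 against it) and Ccl5 at 6308 CPM in cDC2 II and 100.8 CPM in cDC2 I. Interferon-stimulated genes were lower in cDC1 in 10 of 20 and higher in 0, with a median of -0.93 (-1.10 to -0.43), as for Ifitm3 (-2.06) and Isg15 (-1.09). Inflammatory genes were lower in 7 of 18 and higher in 1, by type in 1 of 14 against cDC2 I and 13 of 19 against cDC2 III. Dissociation and immediate early genes were lower in 3 of 22 and higher in 0, and by type lower in 17 of 22 against cDC2 III. Cell cycle genes were higher in 10 of 21 and lower in 0, with a median of 0.96 (0.81 to 1.04), but this came from cDC1 II, with 22 of 22 higher, as 0 of 14 were higher in cDC1 I. Ccr7 was lower in cDC1, at -3.73, mostly because of cDC2 II (797 CPM), and against cDC2 I (2.52 CPM) the fold was 0.09. The inflammatory and interferon lists lay at percentile 0.00 and the cell cycle list at 100.

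pDC differed from the conventional dendritic cells by the lectin Siglech (6.42, 5.76 to 6.59), Ly6d (6.77), the cytochrome c oxidase subunit Cox6a2 (6.46) and the protease Ctsl (5.34). The interferon-induced membrane protein Bst2 (3.54) and the chemokine Ccl4 (3.15) were also higher. MHC class II genes were lower in 8 of 14 and higher in 0, with a median of -1.21 (-1.27 to -1.09), as for H2-Eb1 at -2.09. Mitochondrially encoded transcripts were higher in 4 of 10, such as mt-Nd4 (1.18), and cholesterol synthesis genes in 3 of 20, namely Insig1, Dhcr7 and Msmo1, with 1 of 20 higher against cDC2 I and 5 of 20 against cDC2 II. Of 4 measured B and plasma cell genes, Mzb1 (2.73) and Cd79b (1.41) were higher. The median of all genes lay at 0.15 in this comparison and at -0.05 with median-of-ratios scaling, and under that scaling the MHC class II median was -1.49.

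The smaller types of each conventional class differed from its type I. In cDC1 II all 22 measured cell cycle genes were higher than in cDC1 I, with a median of 3.29 (3.02 to 3.36), as for the topoisomerase Top2a (4.78, 4.19 to 5.03) and the mitotic regulator Birc5 (4.37). Dissociation and immediate early genes were lower in 7 of 22, such as Junb (-1.47, -1.64 to -1.04), and inflammatory genes in 4 of 14, such as Cxcl9 (-3.54) and Il1b (-1.80), with 0 higher in either. cDC2 II had more of the chemokine receptor Ccr7 (6.04, 5.68 to 6.41), the actin-bundling protein Fscn1 (5.68) and the chemokines Ccl5 (5.93) and Ccl22 (4.45) than cDC2 I, and less Cd209a (-3.41, -4.24 to -2.98) and Clec10a (-3.25). Its inflammatory genes were higher in 6 of 19 and lower in 0. Against cDC2 I, cDC2 III had 20 of 22 dissociation and immediate early genes higher and 0 lower, with a median of 2.11 (1.78 to 2.48), and 12 of 19 inflammatory genes higher. Il1b (3.85, 3.55 to 4.06) and Dusp1 (3.06) were among these, and outside both lists the nuclear receptor Nr4a2 (3.44) and the activation marker Cd83 (3.05) were higher. The neutrophil transcript S100a8 was lower (-1.02, -1.46 to -0.84), the only 1 of 9 measured to reach 2-fold. The S100a8 level ran from 126 to 1002 CPM over sets in cDC2 III and from 233 to 2298 CPM in cDC2 I. RNA of other cells is not excluded as its source. Without set 1 or set 2 the Ccl5 fold of cDC2 II was 5.15, without set 3 or set 4 it was 6.70, and its Clec10a fold was -4.07 without set 1 or set 4 and -2.44 without set 2 or set 3. The percentile was 100 for the lists that were higher and 0.00 for the 2 lower lists of cDC1 II. The median of all genes lay at 0.11 for cDC1 II, -0.19 for cDC2 II and -0.10 for cDC2 III. In cDC1 II, Camp and Ngp UMIs of set 1 came almost wholly from 1 cell, with 1108 of 1129.

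**Figure D2:**
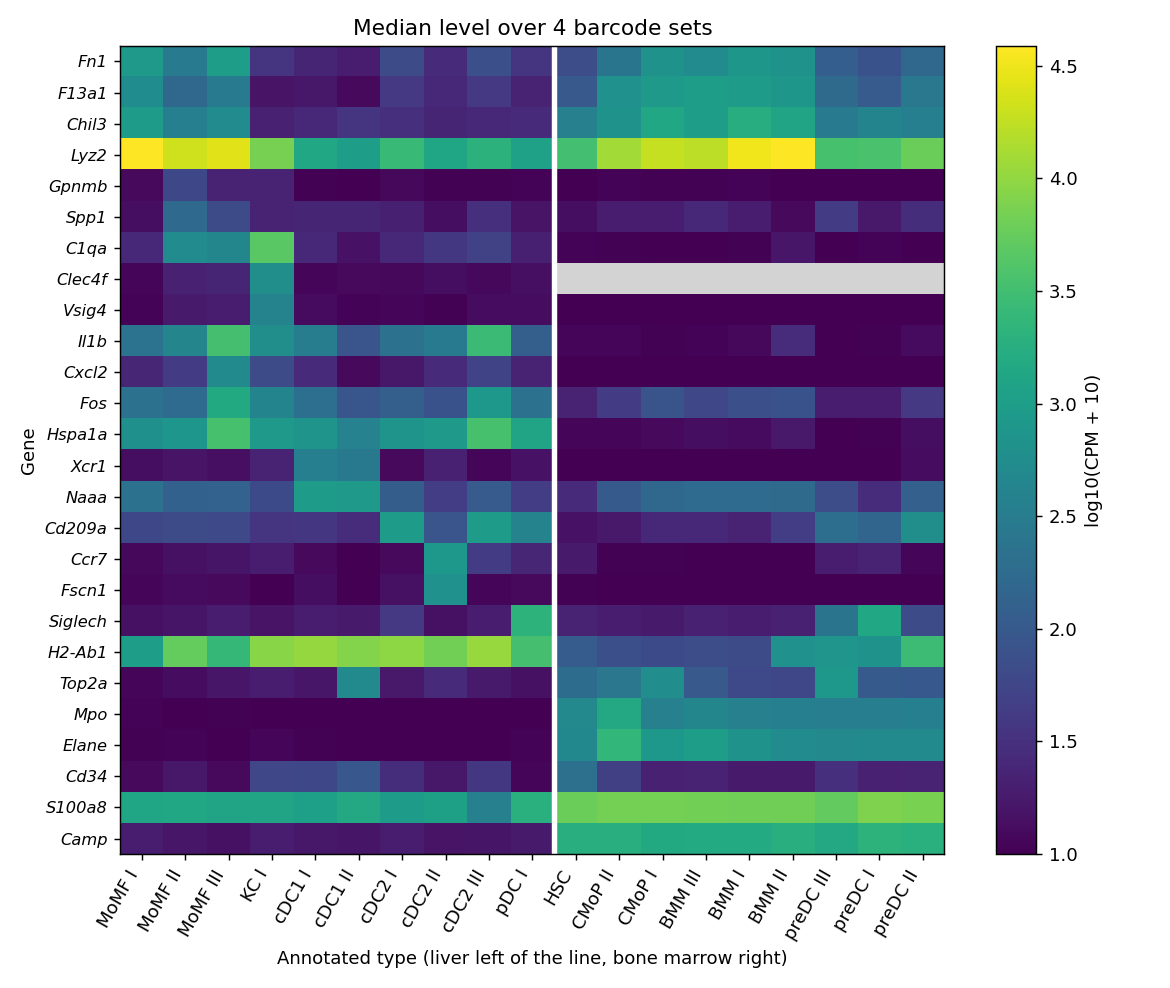
Median level over 4 barcode sets, as log10(CPM + 10) (colour), of marker genes (rows) in each annotated type (columns, liver left of the line and bone marrow right). Clec4f stood at 582 CPM in KC I and between 1.39 and 13.7 CPM in the other liver types, and Elane at 2375 CPM in CMoP II and at most 1.63 CPM in the liver types.

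In bone marrow, CMoP expressed granule, cell cycle and lipid-associated genes more than HSC. The transcription factor Klf4 (3.05, 2.87 to 3.32), the coagulation factor F13a1 (2.92), fibronectin Fn1 (2.65) and the chemokine receptor Ccr2 (2.57) were higher. The lymphoid polymerase Dntt (-4.71, -5.02 to -4.36), the carbonic anhydrases Car2 (-4.66) and Car1 (-4.24) and the transcription factor Sox4 (-3.61) were lower. Granule genes were higher in 10 of 18 and lower in 0, with a median of 1.20 (1.13 to 1.36), cell cycle genes in 14 of 22 and 0, and lipid-associated genes in 8 of 14 and 2. By type, granule genes were higher in 7 of 18 in CMoP I and 10 of 18 in CMoP II, and cell cycle genes in 13 of 22 in CMoP I, with 2 lower, and 6 of 22 in CMoP II. Glycolysis genes were higher in 5 of 15 and lower in 1, led by Eno1 (1.36) and Pkm (1.17). Fatty acid oxidation genes split, with Plin2 and Ucp2 higher (0.97 and 0.72 in CMoP II), Hilpda lower and 11 not counted. The HSC type held other lineages' transcripts, with all 10 measured erythroid genes and 5 of 6 T and NK cell genes lower in CMoP. Of the Hbb-bs UMIs of HSC in set 2, 1741 of 1941 came from 1 cell, and the Hbb-bs fold ran from -5.50 to -0.54 over sets. S100a8 (0.16, -0.20 to 0.52) and S100a9 (-0.03) did not separate them. Percentiles were 100 for the granule, cell cycle, lipid and glycolysis lists and 0.00 for the erythroid and T and NK lists.

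BMM had fewer transcripts of cell cycle genes than CMoP, and BMM II had more of MHC class II and interferon-stimulated genes. Cell cycle genes were lower in 19 of 22 and higher in 0, with a median of -1.45 (-1.61 to -1.31), as for Top2a at -2.60. Interferon-stimulated genes were higher in 13 of 19 and MHC class II genes in 5 of 8, with 0 lower in either. Examples are the invariant chain Cd74 (3.03, 2.85 to 3.25), H2-Aa (2.23) and Isg15 (1.79), beside Apoe (2.28). These values came mostly from BMM II, with 6 of 9 MHC class II and 16 of 21 interferon-stimulated genes higher, while BMM I had 1 of 8 and 5 of 15 and BMM III 0 of 8 and 0 of 12. Cd74 stood at 4.42 in BMM II, 0.55 in BMM I and 0.06 in BMM III. In BMM III 8 of 22 cell cycle genes were lower and 3 higher. The granule proteases Prtn3 (-1.42), Ctsg (-1.39), Elane (-1.32, -1.75 to -0.96) and Mpo (-1.24) were lower, which held against CMoP II, as for Elane (-1.86) and Mpo (-1.85), and not at 2-fold against CMoP I (-0.30 and 0.05). Within BMM, BMM II had more Cd74 (3.91, 3.46 to 4.16), H2-Aa (3.49) and the antiviral gene Ifit3 (2.11) than BMM I, with 5 of 9 MHC class II and 9 of 21 interferon-stimulated genes higher. In BMM III 12 of 22 cell cycle genes were higher than in BMM I, led by Cdc20 (2.91) and Cenpa (2.71). CMoP II stood above CMoP I in Mpo (1.91, 1.60 to 2.51) and Elane (1.55) and in the replication genes Ung (2.14) and Mcm2 (1.68), and below it in mitotic genes such as Ube2c (-3.02). Its cell cycle list split into 5 higher and 12 lower of 22, with a median of -1.18 (-1.21 to -1.07). Percentiles were 0.00 for the cell cycle lists of BMM and CMoP II and 100 for the other lists counted here.

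In preDC, the genes furthest above BMM included Siglech at 5.05 (4.92 to 5.22), Ly6d at 4.97, Cox6a2 at 4.77 and the transcription factor Tcf4 at 3.49. Siglech, Cox6a2 and Tcf4 are among the fixed markers of plasmacytoid dendritic cells. Lysozyme Lyz2 (-2.93), Mgst1 (-3.30) and the Fc receptor Fcgr3 (-2.71) were lower. Interferon-stimulated genes were lower in 12 of 19 and higher in 1, Bst2 (3.21), with a median of -1.20 (-1.29 to -1.05). MHC class II genes were higher in 7 of 12 and cell cycle genes in 11 of 22, with 0 lower. The cell cycle difference came mostly from preDC III (20 of 22 higher), with 2 higher in preDC II and 1 higher and 3 lower in preDC I, and against BMM III 2 were higher and 5 lower in preDC. Of the MHC class II genes 2 of 12 were higher and 1 lower against BMM II, and 1 of 14 interferon-stimulated genes was lower against BMM III. Ly6d and Cox6a2 did not reach 2-fold in preDC II (0.72 and 0.74). The 3 preDC types differed as well. Against preDC I, preDC II had less Cox6a2 (-5.08, -5.11 to -4.60) and Siglech (-4.49) and more Plbd1 (3.42) and H2-Eb1 (2.56). In preDC III 17 of 22 cell cycle genes were higher, with a median of 2.40 (2.28 to 2.44), and 0 lower. Percentiles were 0.00 for the interferon list against BMM and 100 for the MHC class II and cell cycle lists. The median of all genes lay at 0.16 for preDC against BMM and at -0.03 with median-of-ratios scaling.

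Liver MoMF carried more transcripts of inflammatory, immediate early and antigen presentation genes than BMM of bone marrow. Inflammatory genes were higher in 16 of 20 and lower in 0, with a median of 2.28 (2.01 to 2.55), as for Il1b at 6.03 (5.16 to 6.86) and Ccl4 at 4.39. The heat shock gene Hspa1a (chromosome 17, 34969190 to 34972156) had the largest fold, 6.47 (6.18 to 6.97), at 1226 against 4.79 CPM. Its near-identical copy Hspa1b stood at 4.87, and reads of the pair cannot be assigned with certainty. Dissociation and immediate early genes were higher in 18 of 22, with a median of 1.69 (1.32 to 2.01). C1qb (4.58), H2-Eb1 (3.76) and Cd74 (3.03) were higher, as were 8 of 12 MHC class II genes. In MoMF I, II and III against BMM, 11 of 16, 15 of 19 and 18 of 21 inflammatory genes were higher, 11 of 21, 12 of 21 and 21 of 22 dissociation and immediate early genes, and 4 of 12, 12 of 13 and 8 of 13 MHC class II genes. Lower were 21 of 22 cell cycle genes, with a median of -2.19 (-2.32 to -1.96), and 13 of 19 granule genes, with a median of -2.48 (-4.03 to -0.83). The latter included Camp (-6.62, -7.45 to -5.48), Ngp (-6.42), Elane (-5.93) and Mpo (-5.13). Camp plus Ngp stood at like levels in every bone marrow type, with medians from 2569 CPM in preDC III to 3883 CPM in preDC I. The Camp and Ngp folds may therefore compare RNA counted in every marrow cell and not expression by BMM. Of 13 neutrophil transcripts, 8 were lower, and 3, Retnlg, Hdc and Chil1, were higher. All genes named held their direction in 16 of 16 pairs of sets. The median of all genes lay at -0.13, and tissue could not be separated from the table it came in or from the effect of digestion on each tissue.

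Between single types of the tissues, MoMF I exceeded BMM I in Hspa1a (5.59, 5.18 to 6.21), Il1b (4.23, 3.64 to 4.55) and Cd74 (4.09), with 13 of 21 interferon-stimulated genes higher, such as Isg15 (2.46), and 21 of 22 cell cycle genes lower. In pDC of liver against preDC I, Ccl4 (7.02, 5.66 to 7.95), Nr4a1 (4.25), Il1b (3.54) and Fos (3.55) were higher, along with 14 of 22 dissociation and immediate early genes. Cell cycle genes were lower in 20 of 22. Apoe and Trem2 diverged, since Apoe was higher in MoMF I than in BMM I (1.92, 0.93 to 2.64) while Trem2 had no common direction (0.06, -0.65 to 0.85). The median of all genes lay at -0.11 for MoMF I and -0.17 for pDC. Ribosomal protein and oxidative phosphorylation genes did not reach 2-fold in either comparison, for any of 22 members each.

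S100a8 and S100a9 (chromosome 3, 90668978 to 90670035 and 90692632 to 90695721), which encode the subunits of calprotectin, differed more between barcode sets than between types in their medians over cells. As the median over cells of UMIs per 10000 UMIs, they stood between 20.4 and 26.0 in the 7 liver types and classes of set 1, and between 12.7 and 19.4 in set 2. The range was 2.24 to 2.90 in set 3 and 1.20 to 1.48 in set 4. In bone marrow the 9 types spanned 75.5 to 87.8, 68.2 to 76.9, 104 to 121 and 99.4 to 114 in sets 1 to 4. In CPM the bone marrow types differed about as much as the sets. Type medians of the 2 genes summed ran from 8888 in preDC III to 13356 in preDC I, and BMM I ran from 8054 to 12910 over sets. Liver cells in clusters without a deposited type that were named neutrophil-like numbered 259, 135, 20 and 9 in sets 1 to 4, and a further cluster with neutrophil and haemoglobin genes held 157, 135, 16 and 12. Between MoMF and BMM, S100a8 differed by -2.48 (-4.64 to -0.81) and S100a9 by -2.14 (-4.32 to -0.40). Without liver set 1 or 2 these folds were -3.32 and -3.09, and without liver set 3 or 4 they were -1.66 and -1.26. Between pDC and preDC I the S100a8 fold ran from -5.34 to 0.78, so no direction held. These genes were picked by the study from these libraries, so the granule list that holds them is not independent evidence.

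**Figure D3:**
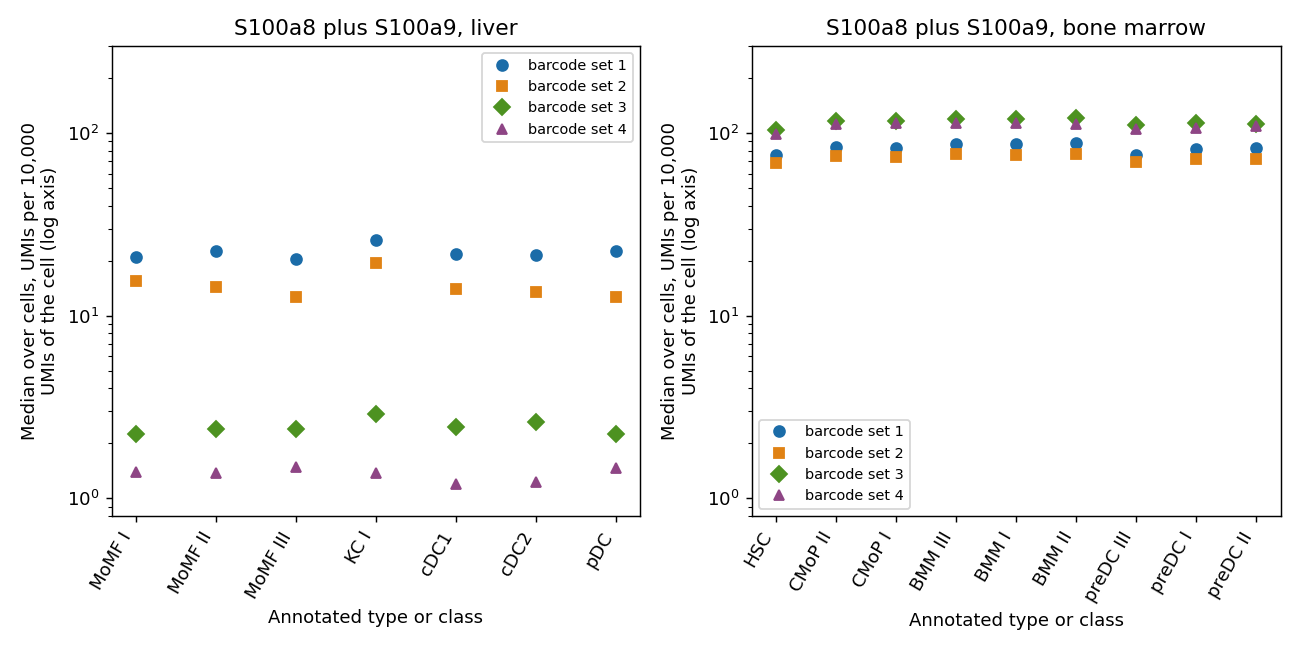
Median over cells of S100a8 plus S100a9 UMIs per 10000 UMIs of the cell (vertical log axis) by annotated type or class (horizontal axis) in liver and bone marrow; each point is 1 of 4 barcode sets. Within each liver set the types lay close together, from 20.4 to 26.0 in set 1 and from 1.20 to 1.48 in set 4, and the bone marrow types lay between 68.2 and 121 over all sets.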

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

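Among the cells without a deposited type, which no comparison uses, clusters stood apart by marker genes of other blood cells. The counts are of cells in clusters named by the marker rule, and no test of them was made. In liver, clusters of 707 cells were named patrolling monocyte-like (Ace, Eno3 and Ear2, with Cd300e in the cluster of 442) and clusters of 423 cells neutrophil-like (S100a8, S100a9, Retnlg). A cluster of 463 cells was named basophil or mast cell-like (Mcpt8, Fcer1a, Prss34, Cpa3), a cluster of 205 cells B cell-like (Cd79a, Ebf1, Ms4a1) and a cluster of 50 cells plasma cell-like (Jchain, Mzb1). The rule left unnamed a liver cluster of 320 cells with neutrophil and haemoglobin genes and a cluster of 98 cells with basophil genes, so these counts are not totals of such cells. In bone marrow, clusters of 1440 cells were neutrophil-like (S100a8, S100a9, Camp, Ngp), 505 cells granulocyte-monocyte progenitor-like (Elane, Ms4a3, Mpo, Prtn3) and 405 basophil or mast cell-like. Patrolling monocyte-like cells numbered 211, erythroid cell-like (Car1, Car2, Klf1) 75 and plasma cell-like 55. The gate excluded Ly6G and CD19, yet neutrophil genes marked clusters in both tissues and B cell genes marked a cluster in liver. The liver basophil or mast cell-like group held 386, 74, 0 and 3 cells in barcode sets 1 to 4, the B cell-like group 83, 93, 11 and 18, and the patrolling monocyte-like group 188, 121, 179 and 219.

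For the patterns weighed next, the tests of a small part of the cells in liver, both bone marrow tests, both tests of the immediate early genes and the test of hepatocyte genes without Hp and Trf were chosen after the result was seen. No biological explanation was tested, because the diet of a barcode set is not known.

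S100a8 and S100a9 UMIs were found in liver cDC1, cDC2 and pDC. Free RNA from cells rich in these transcripts stays open. In 2 of 4 sets the highest of the 3 classes lay within 2 times of the lowest, as CPM or as UMIs per cell. The smaller of these 2 ratios ran from 1.18 to 3.20 over sets. A small part of the cells, such as cells joined to a neutrophil, may carry most of these UMIs as well: the tenth of the cells with the most held 55.7% to 81.6% of them, over 50% in 12 of 12 values. The neutrophil-like cells without a type, which the Ly6G gate should remove, are a candidate source. The data leave both explanations open, and they can hold together.

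In bone marrow, S100a8, S100a9, Camp and Ngp UMIs were found in all 9 types. RNA of 1 source, such as the neutrophil-like cells, counted in cells of every type is a candidate explanation, since within a set the ratio of Camp plus Ngp to S100a8 plus S100a9 differed by at most 1.28 times between types and lay between 0.232 and 0.322 over all sets and types. An equal number of counted free UMIs in every droplet cannot be the whole source. The median UMIs of the 4 genes per cell were 2.79 to 3.04 times as high in CMoP II as in preDC I within sets. Total UMIs per cell differed in the same direction, with medians of 15149.5 in CMoP II and 5375 in preDC I. Free molecules captured at unlike rates by the droplets are therefore not excluded. How such RNA would scale with the RNA content of a cell was not tested. Single cells rich in these transcripts may add to the level of some types, which was not tested either. Relative to counting error, the variance of Camp plus Ngp UMIs over cells had medians over sets of 100 to 110 in preDC I, preDC II, HSC and CMoP II. It was 25.6 in BMM II and 1.09 to 1.20 in BMM I, BMM III, CMoP I and preDC III.

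Immediate early genes stood high in MoMF III and cDC2 III. Within every set the summed list was at least 3.09 times as high in type III as in type I. This cannot decide on a handling difference between whole libraries, because the types may have been drawn by these same genes. By set 1 to 4, MoMF III made up 6.85%, 5.45%, 10.5% and 14.9% of annotated liver cells. The shares of cDC2 III were 2.11%, 2.08%, 4.53% and 7.35%. A response of part of the cells to tissue digestion and sorting cannot be told apart from a state of these cells in the tissue, with ratios up to 5.46, because no undigested cells were profiled. The list summed to 19287 to 22957 CPM in MoMF III, 4666 to 6091 CPM in MoMF I and 2882 to 4495 CPM in the bone marrow types.

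In liver cDC1 II, 1 of 164 cells held 1108 of 1135 Camp and Ngp UMIs, the tenth of the cells with the most held 99.4%, and the share of cDC1 marker UMIs in that cell was 0.126 times that of the others. The summed hepatocyte genes differed by at least 4.30 times between KC, MoMF, conventional dendritic cells and pDC, both as CPM and as UMIs per cell. The smaller of these ratios reached 10.9 over sets. Without Hp and Trf the difference was at least 3.41 times. With the cells of all sets summed, Alb stood at 40.4 CPM in KC and 5.11 CPM in MoMF, and Hp at 47.9 CPM in KC and 683 CPM in MoMF. Since Hp also stood at 1200 CPM in BMM I of bone marrow, summed in the same way, its difference cannot be read as hepatocyte RNA alone. Single cells also held much of the Hbb-bs UMIs, with 1660 of 2674 in liver cDC1 of set 4.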

How the results depend on the processing

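Pseudocounts of 1 and 100 CPM, cells of all barcode sets summed, the median of sets for shares and leaving out each barcode set were chosen after seeing the data. No paired analysis was possible because the cells carry no replicate numbers of the diet groups, which concerns the diet alone, since types were compared within each barcode set. The planned diet tests with DESeq2, a replicate block, a fit of all 8 samples, TMM, TMM over types, camera and fry were not run, since no sample could be assigned to its cells. A minimum of 1000 UMIs removes no cell, so it tests nothing, and types that share a name were used as classes from the start. Thinning to 1500 UMIs left out 1 liver cell and 0 bone marrow cells. Of 7500 gene folds under settings other than leaving out a set, 1874 left the range over sets and 891 moved by over 1.5 times. A median of 3 sets cannot leave that range, and of 6904 folds with a set left out 140 moved by over 1.5 times. The sign changed in 81 and 77 of these, none of them for a gene at 2-fold with 1 direction over sets. Such a gene cannot change sign when a set is left out or the pseudocount is changed. For these genes only scaling, thinning and the sum of all sets could have shown a change of sign. Of 1896 list medians under the other settings 448 left the range over sets and 96 changed sign, and of 1464 with a set left out 29 and 95 did. Among the sign changes, 1 was of a list with 1 direction over sets and a percentile in the outer 5%. Of 2164 list counts 562 moved by over 1.5 times, and of 48 shares 25 moved. The neutrophil transcripts of KC against MoMF turned from -0.35 to 0.13 with the cells of all sets summed, and the cause was not tested. Cells per set numbered 23 to 85 in cDC1 II, 24 to 218 in cDC2 III and 44 to 104 in KC, and at the depth of cDC1 II simulated 4-fold differences were called in 99% and 2-fold ones in 27% of genes, with counting error only.

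With a pseudocount of 1 CPM, list medians (log2) were 3.59 for Kupffer cell genes in KC, 1.44 for lipid-associated and 1.87 for MHC class II genes in MoMF II, 1.95 for inflammatory genes in MoMF III, -1.42 for MHC class II genes in pDC and 3.92 for cell cycle genes in cDC1 II. They were 2.79 for MHC class II genes in BMM II, -1.72 for interferon-stimulated genes in preDC, and 3.43 for inflammatory and -3.46 for cell cycle genes in MoMF against BMM. With 100 CPM they were 0.77 for Kupffer cell genes, 0.47 and 0.62 in MoMF II, and 0.61 for inflammatory and 1.58 for dissociation genes in MoMF III. In dendritic cells they were -0.24 for interferon-stimulated genes in cDC1, -0.67 in pDC, 1.22 in cDC1 II and 1.67 for dissociation genes in cDC2 III. In bone marrow they were 0.85 for granule genes in CMoP against HSC, -0.97 for cell cycle genes in BMM, 0.70 in BMM II, -0.85 for cell cycle genes in CMoP II and -0.24 in preDC, and for MoMF against BMM they were 0.84 and -0.56. A larger pseudocount shrinks folds and a smaller one widens them by construction.

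For the alternatives that follow, the cause of a move was not tested. With cells thinned, medians were 1.02 for lipid-associated genes in MoMF II, 1.11 for granule genes in CMoP, -1.72 for cell cycle genes in BMM and -1.39 for interferon-stimulated genes in preDC. With median-of-ratios scaling they were -1.49 for MHC class II genes in pDC and 1.38 for granule genes in CMoP. Without a filter on low levels they were 1.27 for inflammatory genes in MoMF III, 0.97 for granule genes in CMoP, 0.65 for MHC class II genes in BMM II and 1.92 for inflammatory genes in MoMF against BMM. The median of sets gave shares of 45.1% for MoMF and 18.4% for cDC1, and a denominator without HSC gave 55.0% for BMM, 28.8% for CMoP and 16.2% for preDC.

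Leaving out each barcode set gave shares of 43.6% to 51.1% for MoMF, 2.09% to 2.99% for KC, 12.3% to 19.3% for cDC1, 25.2% to 26.9% for cDC2 and 7.57% to 8.85% for pDC. In bone marrow it gave 49.9% to 52.6% for BMM, 25.9% to 28.2% for CMoP, 14.7% to 15.9% for preDC and 6.07% to 7.06% for HSC. List medians ran from 1.34 to 1.58 for inflammatory genes in MoMF III and from -1.27 to -1.16 for MHC class II genes in pDC, and the Kupffer cell median of KC from 1.77 to 2.82.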

Other observations

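Several clusters of liver cells without a deposited type fell under no marker class by the rule used. A cluster of 290 cells, with a median of 13988 UMIs, had G0s2, the chemokine Cxcl2 and the cystine transporter Slc7a11 among its leading genes. Another of 373 cells combined the granule protease Elane with cell cycle genes such as Top2a and Ube2c. In a cluster of 142 cells the T cell receptor component Cd3d stood beside Nkg7 and the chemokine receptor Cxcr6, although CD3 was excluded by the gate. Basophil genes such as Mcpt8 went together with Il6, Gzmb and Ccl3 in a cluster of 98 cells. Retnlg and S100a8 stood with haemoglobin genes in a cluster of 320 cells, the progenitor genes Sox4 and Cd34 marked a cluster of 96 cells, and Prg4, Alox15 and Vsig4 marked a cluster of 20 cells with a median of 16153 UMIs.

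In bone marrow, a cluster of 502 cells had Pf4, Cd34 and Mpo, a cluster of 327 cells Kctd14, Ube2c and Aurkb, and a cluster of 131 cells Mpo, Calr and mt-Nd1. The annotated cells had at most 2998 genes in liver and 3998 in bone marrow, and 365 and 659 of the cells without a type had more than that. In bone marrow these included 317 of the cluster of 502, 199 of the cluster of 327 and 72 of the 75 erythroid cell-like cells. In liver they included 155 of the cluster of 373 and 166 of the cluster of 290. Whether such cells were doublets was not tested.

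By barcode set 1 to 4, MoMF II made up 6.74%, 8.05%, 20.3% and 18.0% of annotated liver cells, MoMF III 6.85%, 5.45%, 10.5% and 14.9%, and cDC1 I 23.9%, 24.6%, 9.17% and 8.56%.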
